A study of Mus musculus with 9 samples.

How the data were processed

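RNA of the colon was measured in 9 mice, 3 in each of the control, UC model and JPHZW groups, and the labels call the 3 libraries of a group biological replicates. Groups were taken from the sample names. Libraries were made from polyA RNA and read on an Illumina HiSeq instrument. The submitters' processing notes name HISAT2, HTSeq 0.13.5 and GRCm38. The strand of counting, the annotation release and any filter are not given in the sources used here. Per the file headers, each deposited file holds a count per Ensembl gene, not normalized. Each deposited file also holds an FPKM value, which the authors made from the count of the same gene, a gene length and the total count of the file. This was checked: dividing the count by the FPKM and the file total gave a whole-number length for 100% of values, within a relative tolerance of 1e-06.

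The files list 28550 genes, of which 28463 were matched by Ensembl identifier to GENCODE M21 for symbols and positions (GRCm38). Among the genes tested, 13529 were matched, and 20 symbols belong to more than 1 gene. A gene was tested if its FPKM was at least 1 in at least 3 of the 9 libraries, which left 13539 genes holding between 99.0% and 99.5% of each library's counts. The total per library ranged from 14778816 to 17103810.

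The design fixed before the data were examined assumed FPKM values alone and a limma fit on log2(FPKM + 1). Because the files also hold counts, the tests reported here use counts, and that limma fit is an alternative. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, two-sided, TMM factors, 1 mean per group over all 9 libraries), and p-values were adjusted by Benjamini-Hochberg over the genes tested and called at 0.05. Each SE is the size of the log2 fold change divided by the square root of F. CPM values are TMM-scaled, and the prior count of 2 was used for log2 CPM only. An exact permutation of 3 against 3 libraries has 10 splits and cannot give a p below 0.1, so no single value was tested that way. A fold against a group with 0 counts was bounded by 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact 95% counting interval.

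Before the data were examined, 38 gene lists were fixed from textbook knowledge of the colon, of colitis and of the pathways in the design text. The 36 lists with at least 5 tested members were tested with camera of limma 3.58.1 on z-scores of the edgeR counts, with a preset correlation of 0.01 between genes, and again with an estimated correlation. Genes were named by a rule fixed at the same time. In the UC model against control and in JPHZW against the UC model it takes the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose groups do not overlap, and in JPHZW against control 5 each way. Predicted genes, clone names and antigen receptor segments are left out. Where fewer pass, the named genes are filled to 4 each way by the smallest unadjusted p. Pparg, Nfkb1, Rela, Nfkbia, Tnf, Il1b and Il6 are always named. From each list up to 4 members that passed are named by the smallest p, or 1 or 2 where none passed. Some members that this rule takes are not reported here.

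Alternatives included other pseudocounts, filters, scalings, thresholds and fits, a replicate block, DESeq2 1.42.0 and each library left out in turn. The effect of shared libraries was simulated in 40 draws that treat genes as independent. The fit was tested on simulated counts. Of these, 100 genes changed 2-fold and 100 changed 4-fold in each comparison with control, and 200 and 200 in JPHZW against the UC model. It recovered 74%, 76% and 72% of 4-fold and 12%, 21% and 25% of 2-fold changes in the UC model against control, JPHZW against the UC model and JPHZW against control, and 10.4%, 6.73% and 4.90% of its calls were false. In simulated data for the UC model against control, camera found the shifted list (adjusted p = 1.88e-33) and called 0 of the unshifted ones. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.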

Results

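RNA was sequenced from the colon of 9 male C57BL/6 mice in 3 groups of 3. Control mice drank distilled water. The UC model mice drank dextran sodium sulfate, a detergent-like polymer that injures the colon epithelium and gives a colitis used to model ulcerative colitis (UC), at 3% for 4 days and then at 2% for 6 days, followed by saline. The JPHZW mice had the same colitis and were then given Jianpi Huazhi Wan (JPHZW), a traditional Chinese medicine preparation, by gavage at 200 mg/kg for 7 days per the series' design text. The treatment label of these libraries also names olsalazine, an aminosalicylate, so it stayed open whether these mice received JPHZW alone. The design text puts collection on day 15, which the days of dextran sodium sulfate and gavage in the labels do not add up to, and the labels do not say which part of the colon was taken. Each library held between 14778816 and 17103810 counts, and 13539 genes entered the tests. Expression levels are given as CPM (counts scaled to a common library size) with the SD over n = 3 libraries, fold changes as log2 values with their SE, and adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counting intervals and lower bounds on folds cover counting error only.

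Genes of neutrophils, fibroblasts and B cells set single libraries apart within the groups. The mean log2 CPM of the neutrophil genes, centred over the 9 libraries, was 3.33 in UC model 3 and 3.75 in JPHZW 3, against 0.56 and -0.78 in UC model 1 and 2 and 1.51 and 1.17 in JPHZW 1 and 2. The fibroblast genes were highest in JPHZW 3 at 2.61, and the B cell and germinal centre genes in JPHZW 2 at 4.27 and control 1 at 1.89. Along the first principal component, which held 56.1% of the variance, the control libraries lay apart from the others. No pair of libraries within a group differed by as little as sampling noise, since the chi-square per degree of freedom ranged from 35.0 to 199.

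**Figure D1:**
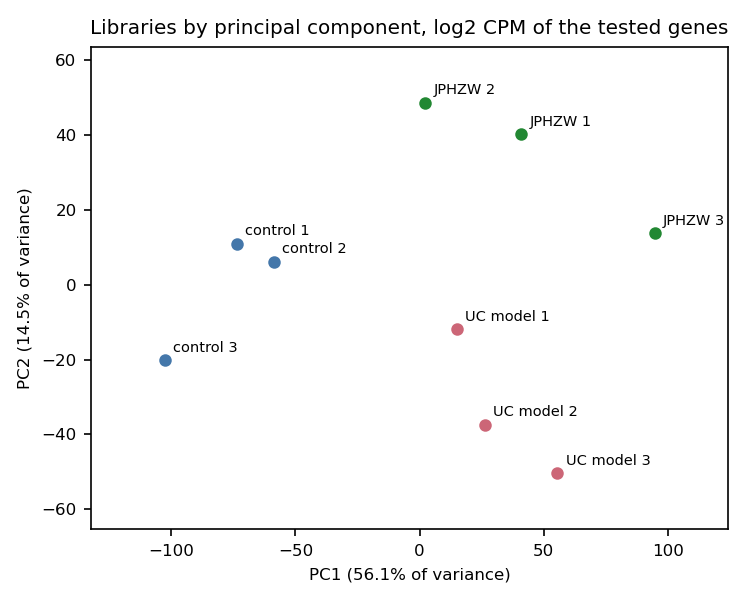
Principal components of log2 CPM over the genes tested, with each point 1 library coloured by group. The axes hold 56.1% and 14.5% of the variance. The control libraries lie between -102.7 and -58.7 on the first component, and JPHZW 3 lies farthest from them at 94.7.

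The comparison of the UC model with control libraries asks which genes change in dextran sodium sulfate colitis. Among the genes that rose was Reg3g, a secreted antimicrobial lectin, which went from 0.199 ± 0.116 to 432 ± 486 CPM (log2 11.03 ± 2.65, adjusted p = 0.0494). Plet1, an epithelial surface protein on chromosome 9 (GRCm38, 50494525 to 50505482), went from 0.511 ± 0.273 to 103 ± 19.4 CPM (log2 7.64 ± 0.70, adjusted p = 0.00562). Among the genes that fell were Vtcn1, an inhibitory B7 family ligand, (log2 -6.16), Fut9, a fucosyltransferase, from 69.6 ± 7.52 to 1.16 ± 0.378 CPM (log2 -5.90 ± 0.73), and Ang4, an antimicrobial ribonuclease, from 313 ± 130.4 to 9.33 ± 9.68 CPM. In all 770 genes differed, 443 of them higher and 327 lower, and 4001 had an unadjusted p under 0.05.

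The other named genes that rose in the UC model were the acute-phase gene Saa3 (log2 9.29), the bile acid transporter subunit Slc51a (7.71) and the transcription factor Osr2 (7.14). Cyp2c66, a cytochrome P450, had 0 counts in the control libraries and 254 in the UC model, at least 82.2-fold higher against a floor of 3 counts over the group. Il1r2, a decoy receptor for interleukin 1, rested on 1 control count, a ratio of 842 with a 95% counting interval from 151 to 33309. Plet1os, antisense to Plet1, had a ratio of 269 (74.1 to 2225), and its reads cannot be told from those of Plet1 because the strand used in counting was not given. Besides Vtcn1, Fut9 and Ang4, the phosphate transporter Slc34a2 (-4.94), Itih2 (-4.79), the sugar phosphate exchanger Slc37a2 (-4.78) and the carboxylesterase Ces1b (-4.73) fell, and Ftdc2 had a control to UC model ratio of 79.3 (13.8 to 3174). Reg3g, Saa3, Cyp2c66 and Ces1b belong to gene families, so their values are uncertain where reads were shared, which was not measured. Single libraries moved these folds by over 1.5 times. Without UC model 3, Reg3g was at 9.52 (adjusted p = 0.101), Saa3 at 7.42 (0.104), Vtcn1 at -7.29 (0.0513) and Il1r2 at a ratio of 91.4 (0.0585). Without UC model 2, Slc51a was at 6.86 (0.0361), Osr2 at 6.23 (0.0302), Slc34a2 at -5.53 (0.0950), Ces1b at -5.44 (0.0736) and Cyp2c66 at least 54.7-fold higher (0.0676). Without UC model 1, Itih2 was at -5.98 (0.0303), Slc37a2 at -6.25 (0.0505) and Ang4 at -6.29 (0.0523), and Ftdc2 had no UC model counts left (0.0839). Without control 1, Slc34a2 was at -3.94 (0.117) and Slc37a2 at -3.48 (0.116), and without control 2 Osr2 was at 8.03 (0.0608), while Plet1os and Il1r2 had 0 control counts (0.0552 and 0.114). The nuclear receptor gene Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399) rose from 40.7 ± 8.28 to 104 ± 28.5 CPM (log2 1.35 ± 0.24, adjusted p = 0.0292). Nfkb1 (0.32, adjusted p = 0.136), Rela (0.37, 0.334), Nfkbia (0.60, 0.192), Tnf (2.22, 0.0662) and Il1b (6.69, 0.0526) did not pass, and Il6 was under the expression filter. Il1b passed without JPHZW 2 (adjusted p = 0.0425) and JPHZW 3 (0.0195), and in 10 of 27 alternatives in all, at 5.01 without UC model 3 and 7.46 without control 1. Tnf was at 1.62 without UC model 1.

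The number of genes called moved by over 1.5 times with each library left out. It was 38, 26 and 16 without control 1, 2 and 3, 376, 154 and 101 without UC model 1, 2 and 3, and 175, 1233 and 1366 without JPHZW 1, 2 and 3, whose libraries enter the estimate of spread. DESeq2 called 2679. List members and Hox genes beyond the named genes enter these omissions only through the totals. Of the 17 named genes that passed, Plet1 stayed past the threshold in each of the 9 omissions, and 2, 1 and 1 passed without control 1, 2 and 3, 9, 6 and 5 without UC model 1, 2 and 3, and 7, 16 and 17 without JPHZW 1, 2 and 3. Pparg had an adjusted p of 0.0792, 0.0824 and 0.0902 without control 1, 2 and 3, of 0.0632 and 0.0728 without UC model 2 and 3, and of 0.0520 without JPHZW 1. The 3 libraries of each group did not overlap for 5200 genes, 38.4% of those tested, where chance gives 10%.

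Genes of myeloid cells were higher in the UC model. For the monocyte and macrophage list, 11 of 19 tested members rose, 8 did not pass, with 17 higher adjusted over the list alone, with Gpnmb (1.70 to 32.3 CPM), the complement gene C1qb (5.61 to 39.9), Cd68 and Ccr2 among them (camera adjusted p = 1.21e-12, and adjusted p = 0.532 with an estimated correlation). In the neutrophil list 2 of 11 tested members rose, 9 did not pass, with 9 higher adjusted over the list alone, the 2 being the growth factor receptor Csf3r (log2 5.96 ± 1.12) and Il1r2 (camera adjusted p = 9.38e-06, and adjusted p = 0.532 with an estimated correlation). The cytokine and chemokine list was higher with 15 of 15 members positive, though none of the 15 tested members passed, with 15 higher adjusted over the list alone (camera adjusted p = 4.8e-07, and adjusted p = 0.532 with an estimated correlation). Its median log2 change was 4.74, or 4.62 with members at 0 to 3 control counts set at their bound or ratio. T and NK cell genes were higher too. In their list, 1 of 13 tested members rose, 12 did not pass, with 6 higher adjusted over the list alone, the 1 being the granzyme Gzma (0.289 to 4.78 CPM) (camera adjusted p = 0.000107, and adjusted p = 0.621 with an estimated correlation). For plasma cells, 3 of 6 tested members rose, 3 did not pass, with 3 higher adjusted over the list alone: Prdm1 (log2 2.89), the antibody joining chain Jchain (3.25) and Derl3 (1.49) (camera adjusted p = 0.00213, and adjusted p = 0.532 with an estimated correlation). NF-kB pathway genes moved less, with a median of 0.36. In the NF-kB list, 2 of 23 tested members rose, 21 did not pass, with 3 higher adjusted over the list alone, and the adhesion molecules Icam1 (2.59) and Vcam1 (2.48) were those that rose (camera adjusted p = 0.00382, and adjusted p = 0.686 with an estimated correlation). UC model 3 held the highest neutrophil score of its group, and without it the medians of the neutrophil and cytokine lists were 5.12 and 4.00. Without control 2 they were 9.18, with Il1r2 left at 0 control counts, and 5.58. The T and NK cell median was 1.08 without UC model 2 and 2.61 without control 1, where the plasma cell median was 2.55.

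Epithelial defence genes were higher too. For epithelial antimicrobial defence, 6 of 16 tested members rose and 1 fell, 9 did not pass, with 9 higher and 2 lower adjusted over the list alone, including the oxidase Duox2 (89.9 to 272 CPM), the protease inhibitor Slpi (log2 5.75), Nos2 (4.15) and Ido1 (4.89), and the 1 that fell was Ang4 (camera adjusted p = 0.00382, and adjusted p = 0.532 with an estimated correlation). Reg3b, at 0 counts in control libraries, was at least 32970-fold higher, or 12762-fold without UC model 3, though it did not pass. The median of the antimicrobial list was 1.59 without UC model 3. In the regenerative epithelium list 2 of 13 tested members rose, 11 did not pass, with 4 higher adjusted over the list alone: the growth factor Areg (2.54) and the urokinase receptor Plaur (3.71) (camera adjusted p = 0.0308, and adjusted p = 0.686 with an estimated correlation). Camera's adjusted p was 0.0782, 0.101 and 0.109 without control 3, UC model 1 and UC model 3. Enteroendocrine genes were higher. In the enteroendocrine list, 3 of 12 tested members rose, 9 did not pass, with 8 higher adjusted over the list alone, namely Scg2 (1.65), somatostatin Sst (2.15) and neurotensin Nts (7.10) (camera adjusted p = 0.000827, and adjusted p = 0.532 with an estimated correlation). The stem cell and Wnt list was lower, with the stem cell transcription factor Ascl2 going from 25.4 to 4.37 CPM. In the stem cell list, 1 of 14 tested members fell, 13 did not pass, with 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00793, and adjusted p = 0.621 with an estimated correlation). Oxidative stress and Nrf2 genes were higher with a median of 0.34. In the Nrf2 list, none of the 17 tested members passed, with 3 higher adjusted over the list alone, led by Gpx3 (3.07) and Srxn1 (1.19) (camera adjusted p = 0.0208, and adjusted p = 0.621 with an estimated correlation), and the adjusted p was 0.0731 without control 1 and 0.0745 without UC model 3. Mitochondrially encoded transcripts were lower with 0 of 13 positive. In the mitochondrially encoded list, none of the 13 tested members passed and none passed adjusted over the list alone, with mt-Nd2 at -0.70 (camera adjusted p = 0.0192, and adjusted p = 0.806 with an estimated correlation). The adjusted p was 0.156 without control 3 and 0.148 without UC model 3.

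Genes of the gut wall were higher as well. Enteric neuron, glia and interstitial cell of Cajal genes moved with the neuronal genes Uchl1 (log2 2.23) and Tubb3 (2.61) and the peptide gene Vip (2.63). In the enteric neuron list, 8 of 15 tested members rose and 1 fell, 6 did not pass, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.93e-07, and adjusted p = 0.532 with an estimated correlation). In the extracellular matrix and remodelling list, 24 of 24 members were positive and 1 of 24 tested members rose, 23 did not pass, with 14 higher adjusted over the list alone (camera adjusted p = 7.55e-08, and adjusted p = 0.621 with an estimated correlation). The 1 was the matrix protease Mmp7, with 2 control counts and a ratio of 142 (39.0 to 1179), which was 49.3 without UC model 3. The endothelial list, with Esam at 1.25, was higher though none of the 13 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.00184, and adjusted p = 0.697 with an estimated correlation). Fibroblast genes, with Pdpn at 2.49, were higher though none of the 13 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.00382, and adjusted p = 0.701 with an estimated correlation). Smooth muscle genes had a median of 0.78, with Mylk at 1.16. In the smooth muscle list, none of the 13 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.0300, and adjusted p = 0.889 with an estimated correlation). That last call was lost without control 1, control 3, UC model 1, UC model 2 and JPHZW 3, at adjusted p of 0.0993, 0.183, 0.0521, 0.234 and 0.0644. Without control 2 the medians of the matrix, fibroblast and smooth muscle lists were 3.37, 2.57 and 1.44, and without UC model 3 the matrix median was 1.81.

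Single genes changed in several lists that camera did not call in the UC model. In the goblet cell and mucus list 3 of 20 tested members rose and 1 fell, 16 did not pass, with 5 higher and 1 lower adjusted over the list alone: the mucin Muc2 rose from 1582 ± 488 to 9439 ± 736 CPM (adjusted p = 0.0135), B3gnt6 and Spdef rose, and Clca1 fell from 4075 to 627 (camera adjusted p = 0.328, and adjusted p = 0.701 with an estimated correlation). Among absorptive colonocyte and ion transport genes 3 of 23 tested members rose and 4 fell, 16 did not pass, with 6 higher and 5 lower adjusted over the list alone, with the carbonic anhydrase Car1 up from 259 to 4089.6 CPM, the sodium channel subunit Scnn1b up and Slc20a1 and Slc16a1 down (camera adjusted p = 0.793, and adjusted p = 0.974 with an estimated correlation). For xenobiotic metabolism, 3 of 25 tested members rose and 2 fell, 20 did not pass, with 7 higher and 4 lower adjusted over the list alone: Cyp2c65 (5.72) and Ugt1a1 (2.81) rose, and Maob (-1.74) and Adh1 (-3.08) fell (camera adjusted p = 0.813, and adjusted p = 0.974 with an estimated correlation). In PPAR signalling and targets 2 of 23 tested members rose and 1 fell, 20 did not pass, with 8 higher and 2 lower adjusted over the list alone: Pparg and Me1 (2.87) rose and Ppard (-0.76) fell (camera adjusted p = 0.0688, and adjusted p = 0.621 with an estimated correlation), and camera's adjusted p was 0.0296 without UC model 1 and 0.0231 without JPHZW 2. The claudin Cldn4 (2.53) rose in the tight and adherens junction list, where 17 of 18 members did not pass, and 3 higher passed adjusted over the list alone (camera adjusted p = 0.960, and adjusted p = 0.994 with an estimated correlation). Asns (1.55) rose in the unfolded protein response, where 15 of 16 members did not pass, and 1 higher passed adjusted over the list alone (camera adjusted p = 0.332, and adjusted p = 0.889 with an estimated correlation). Mefv (2.70) rose in inflammasome and pyroptosis, where 11 of 12 members did not pass, and 2 higher and 2 lower passed adjusted over the list alone (camera adjusted p = 0.597, and adjusted p = 0.919 with an estimated correlation). The chemokine Cxcl13 (3.73) rose in the B cell and germinal centre list, where 12 of 13 members did not pass, and 1 higher passed adjusted over the list alone (camera adjusted p = 0.761, and adjusted p = 0.974 with an estimated correlation). Ier3 (2.33) rose among immediate early and heat shock genes, where 14 of 15 members did not pass, and 1 higher passed adjusted over the list alone (camera adjusted p = 0.593, and adjusted p = 0.966 with an estimated correlation). The clock genes Clock (-0.72) and Arntl (-0.86) fell in the circadian clock list, where 11 of 13 members did not pass, and 1 higher and 3 lower passed adjusted over the list alone (camera adjusted p = 0.811, and adjusted p = 0.974 with an estimated correlation).

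No member passed in the remaining lists over all genes tested. Adjusted over the list alone, 2 members were higher and 0 lower in fatty acid oxidation, 0 and 1 among mast cell genes, and none passed in the others. With an estimated correlation the adjusted p of the lists tested lay between 0.889 and 0.994. Camera's adjusted p was 0.986 for fatty acid oxidation and ketogenesis, 0.0750 for nuclear genes of oxidative phosphorylation, 0.101 for the interferon response, 0.593 for MHC class II, 0.638 for proliferation, 0.892 for tuft cells, 0.330 for adipocytes, 0.761 for erythroid cells and 0.588 for the distal position genes. The interferon response list, with Iigp1 at 2.81, passed at an adjusted p of 0.0189 without control 3 and 1.14e-06 without UC model 3. MHC class II passed without UC model 3 (0.00570), proliferation without control 3 (0.0115) and the immediate early and heat shock list without control 2 (0.0179). Mast cell and eosinophil genes (4 tested, median 1.60) and skeletal muscle genes (3 tested, median 1.66) were too few for camera. Camera's direction differed in sign from the median, the mean or both in the lists of fatty acid oxidation (median -0.05, mean 0.15), junctions (-0.05, 0.08), inflammasome (-0.21, 0.16), tuft cells (-0.42, -0.03) and circadian clock (0.47, 0.10). Camera called 17 of 36 lists, 15 higher and 2 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.532. Under other settings the call ended on the TPM scale for the antimicrobial, regenerative and smooth muscle lists (adjusted p = 0.0888, 0.0917 and 0.0577), after quantile normalization for mitochondrially encoded transcripts (0.313), with FPKM of at least 5 for smooth muscle (0.0584) and with the distal position covariate for Nrf2 genes (0.0832). Without UC model 3 and JPHZW 3 it ended for mitochondrially encoded, Nrf2 and regenerative genes (0.187, 0.0582 and 0.0538), and without control 1 and JPHZW 2 for Nrf2 and smooth muscle genes (0.0935 and 0.0737). Other settings also called lists not called here: PPAR in 5 settings (adjusted p from 0.0219 to 0.0428), the interferon response in 4 (9.02e-06 to 0.0477), oxidative phosphorylation in 4 (0.0208 to 0.0347), goblet cell genes after quantile normalization (0.0412) and MHC class II without UC model 3 and JPHZW 3 (0.0234).

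Homeobox genes, which set position along the body axis and so along the colon, were in part higher in the UC model. Of 23 Hox genes tested 5 passed, all of them higher, and no lower one passed, the smallest adjusted p among these being 0.0806 for Hoxa6. Hoxb13, whose expression marks the distal colon and rectum, stood at 444, 498 and 411 CPM in the control libraries, 137, 0 and 1.04 in the UC model and 245, 271 and 16.3 in JPHZW libraries, and did not pass in the UC model (adjusted p = 0.270). Hoxb5, Hoxb6, Hoxb7, Hoxb8 and Hoxd8 rose by 3.56, 5.05, 4.59, 6.55 and 3.01 log2 units (adjusted p from 0.0131 to 0.0234). These genes were singled out after their values were seen.

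**Figure D2:**
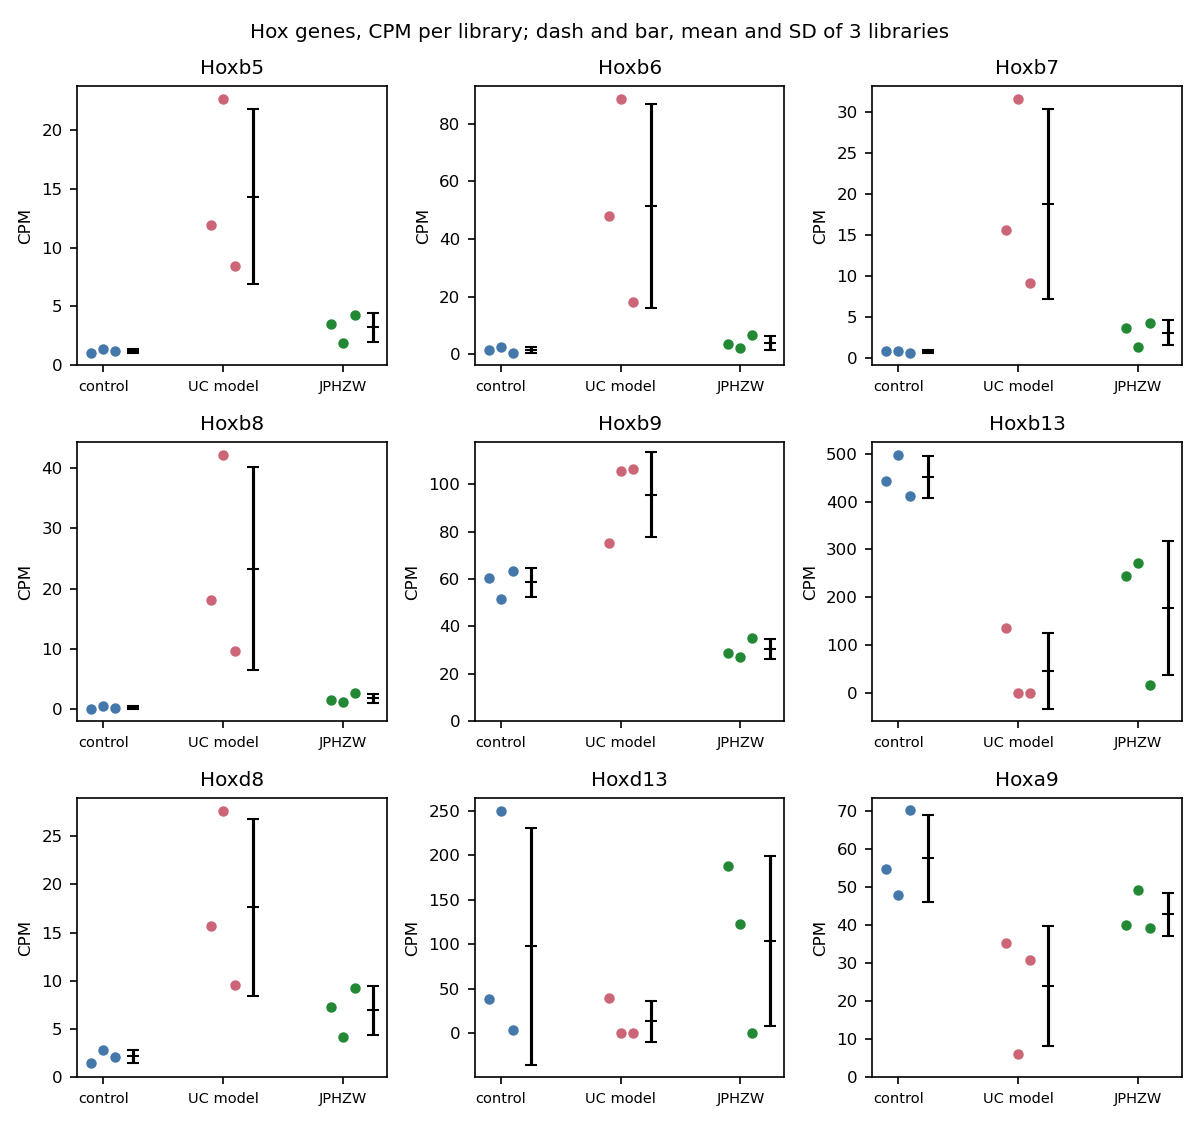
CPM of 9 homeobox genes in each library, with points for the 3 libraries of each group and bars for the mean and SD. Hoxb6 averages 1.55, 51.6 and 4.08 in control, UC model and JPHZW libraries, and Hoxb13 451, 45.9 and 177.

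**Figure D3:**
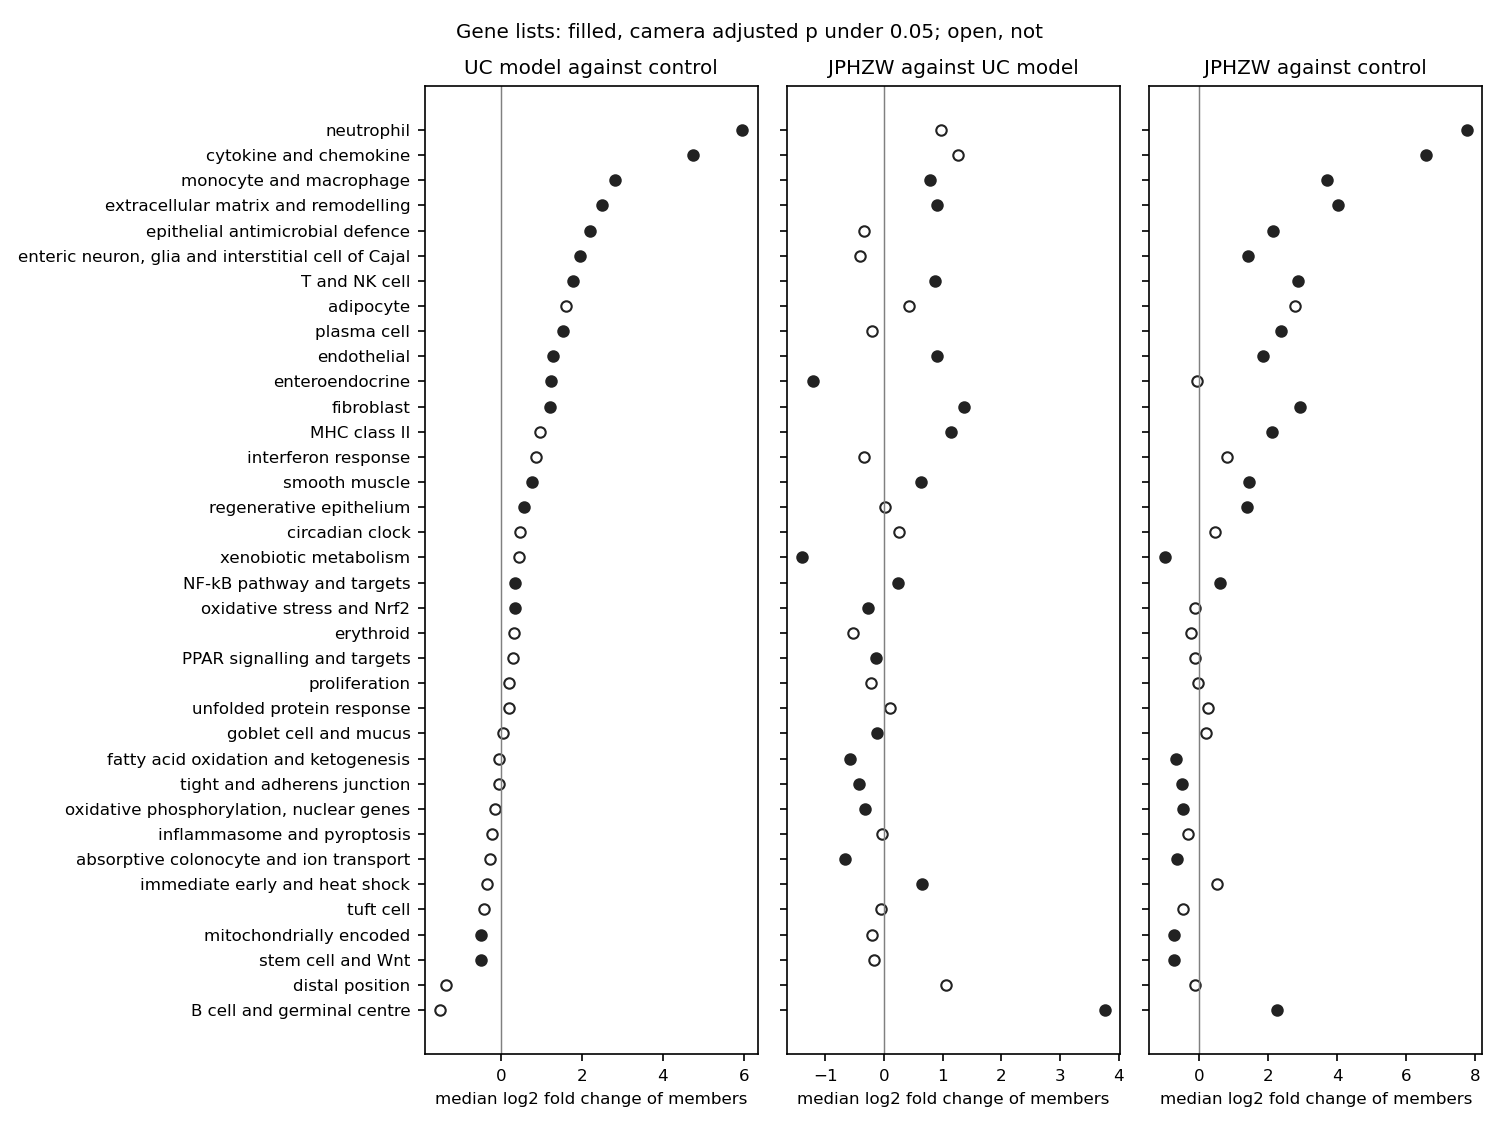
Median log2 fold change of each gene list in the 3 comparisons, with filled points where camera's adjusted p was under 0.05 at the preset correlation. Monocyte and macrophage genes stand at 2.83 in the UC model against control, 0.78 in JPHZW against the UC model (0.12 without JPHZW 3) and 3.71 in JPHZW against control, and fatty acid oxidation and ketogenesis at -0.05, -0.58 and -0.67.

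The comparison of the JPHZW with the UC model libraries asks which genes the treatment regulates. Nupr1, a stress-induced nuclear protein gene (ENSMUSG00000030717, chromosome 7, 126623249 to 126630861), fell from 227 ± 22.4 to 66.4 ± 15.9 CPM, with 43.3 ± 4.90 in control libraries (log2 -1.77 ± 0.19, adjusted p = 0.0406). Hoxb9, a homeobox gene of body-axis position (ENSMUSG00000020875, chromosome 11, 96271457 to 96276595), fell from 95.6 ± 17.8 to 30.4 ± 4.17 CPM, with 58.5 ± 6.12 in control libraries (log2 -1.65 ± 0.18, adjusted p = 0.0406). The other gene that fell, 2210407C18Rik (ENSMUSG00000037145, chromosome 11, 58608204 to 58616075), went from 92.2 ± 29.3 to 8.32 ± 2.84 CPM, with 2.33 ± 0.463 in control libraries (log2 -3.47 ± 0.33, adjusted p = 0.0406). Its clone name lies outside the rule for named genes, and it is named because of its value. These 3 were the genes called, with 0 higher, and 1876 had an unadjusted p under 0.05. At an adjusted p under 0.10 there were 48, 10 higher and 38 lower, and DESeq2 called 572.

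Next in rank, without passing, were Trim46 (15.4 to 36.9 CPM, log2 1.26, adjusted p = 0.0584), the choline transporter-like gene Slc44a2 (0.86, 0.0893), the phosphatase Ssh2 (0.75, 0.0893) and the neuropeptide Y receptor Npy1r (2.12, 0.0893) on the higher side. On the lower side were lactoperoxidase Lpo (log2 -1.96, adjusted p = 0.0584) and the mitochondrial carrier Slc25a10 (-0.92, 0.0795). The design text names the PPARγ and NFκB pathways. Pparg stood at 104 ± 28.5 CPM in the UC model and 42.6 ± 6.65 in JPHZW libraries (log2 -1.29 ± 0.24, adjusted p = 0.110), close to the 40.7 ± 8.28 of control libraries. Nfkb1 (0.12, adjusted p = 0.689), Rela (0.08, 0.893), Nfkbia (-0.01, 0.990), Tnf (0.04, 0.982) and Il1b (1.84, 0.494) did not pass. Single libraries set the direction of some: Il1b was at -0.39 without JPHZW 3 and 3.52 without UC model 3, Tnf at -0.30 without UC model 2 and 0.63 without UC model 1, Rela at -0.14 without UC model 2 and Nfkbia at 0.29 without UC model 3, and none passed. Without a single library the count of genes called was 0 for control 1, 2 and 3, UC model 1 and 2, and JPHZW 1 and 2, 3 for UC model 3 and 17 for JPHZW 3. In the omissions with 0 calls by edgeR, between 1452 and 2295 genes had an unadjusted p under 0.05. Nupr1 and Hoxb9 passed without JPHZW 3 and in none of the other 8 omissions, where their adjusted p lay between 0.0524 and 0.218. The libraries of the groups did not overlap for 2299 genes, 17.0% where chance gives 10%.

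**Figure D4:**
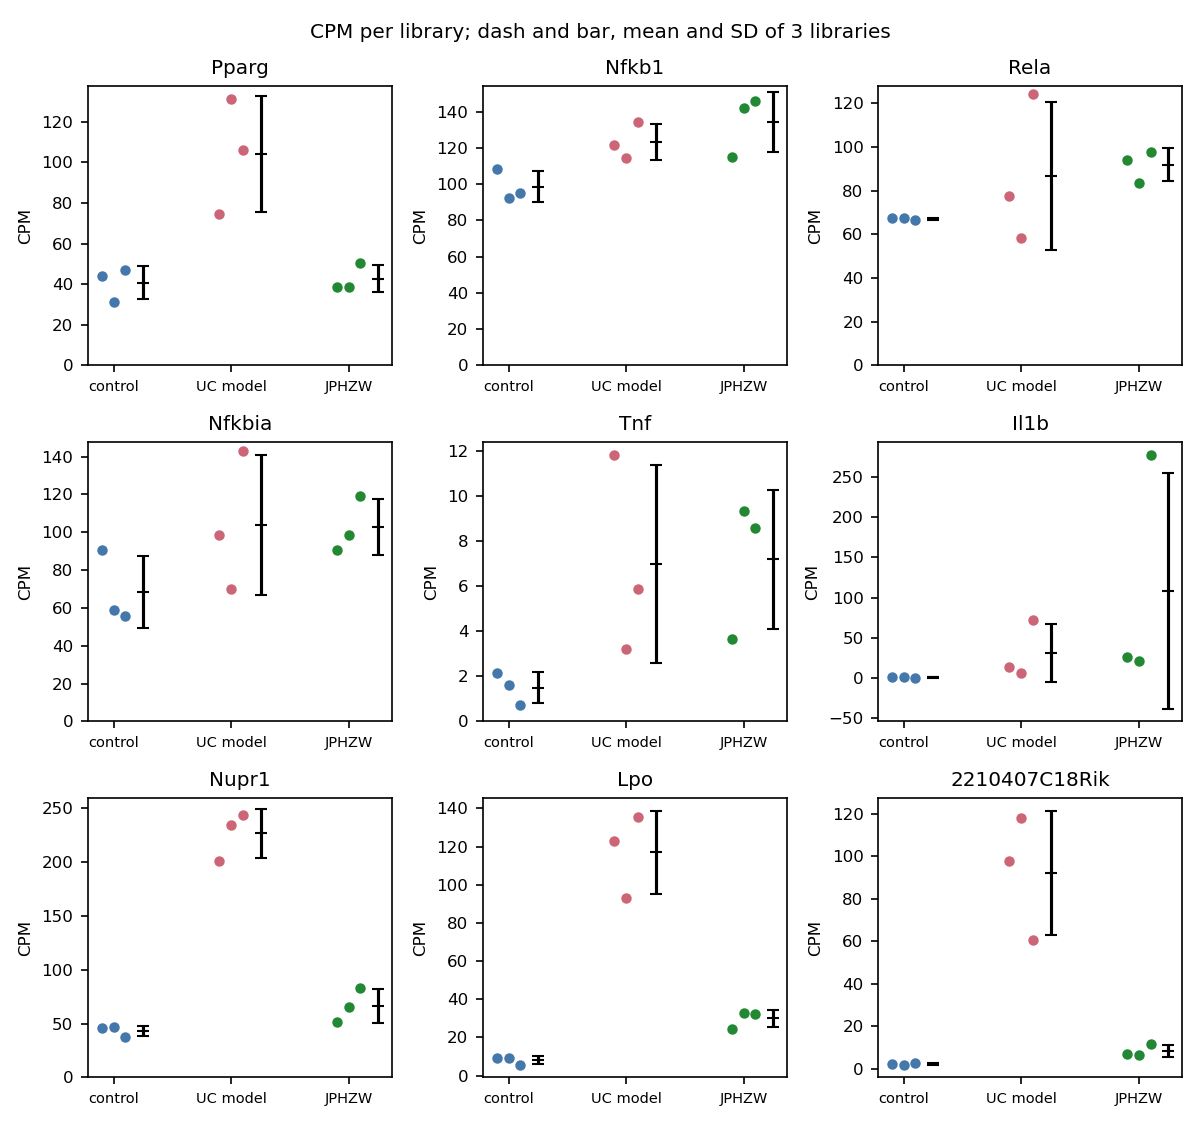
CPM of 9 genes in each library, with points for the 3 libraries of each group and bars for the mean and SD. Nupr1 averages 43.3, 227 and 66.4 and Pparg 40.7, 104 and 42.6 in control, UC model and JPHZW libraries.

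Metabolic and epithelial gene lists were lower in JPHZW than in UC model libraries. For fatty acid oxidation and ketogenesis none of the 18 tested members passed, with 17 lower adjusted over the list alone, and 0 had a positive change, with the carnitine palmitoyltransferase Cpt1a at -0.85 ± 0.13 (camera adjusted p = 3.11e-18, and adjusted p = 0.190 with an estimated correlation). Xenobiotic metabolism had a median of -1.39, with the sulfotransferase Sult1a1 (169 to 57.8 CPM) and Ugt1a1 (-3.77). In the xenobiotic list, none of the 25 tested members passed, with 1 higher and 12 lower adjusted over the list alone (camera adjusted p = 3.24e-18, and adjusted p = 0.190 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 0 of 23 positive, with Cox5a at -0.45. In the oxidative phosphorylation list, none of the 23 tested members passed, with 6 lower adjusted over the list alone (camera adjusted p = 1.13e-08, and adjusted p = 0.442 with an estimated correlation). Enteroendocrine genes were lower, with chromogranin Chga at -1.67 and the serotonin synthesis gene Tph1 at -2.12. In the enteroendocrine list, none of the 12 tested members passed, with 5 lower adjusted over the list alone (camera adjusted p = 5.93e-07, and adjusted p = 0.190 with an estimated correlation). The tight and adherens junction list, with Cldn2 (368 to 181 CPM) and Cldn23 (-1.15), was lower. In the junction list, none of the 18 tested members passed, with 3 lower adjusted over the list alone (camera adjusted p = 3.56e-06, and adjusted p = 0.348 with an estimated correlation). Absorptive colonocyte and ion transport genes had Car1 at -4.24 ± 0.61, from 4089.6 to 216 CPM. In the absorptive colonocyte list, none of the 23 tested members passed, with 4 lower adjusted over the list alone (camera adjusted p = 0.000167, and adjusted p = 0.566 with an estimated correlation). For oxidative stress and Nrf2, with Sod1 at -0.67, none of the 17 tested members passed, with 7 lower adjusted over the list alone (camera adjusted p = 0.000191, and adjusted p = 0.348 with an estimated correlation). Genes shared by all epithelial cells had a median of -0.48 over 15 genes, without a test. Their mean centred log2 CPM was 0.23, 0.02 and 0.25 in UC model 1, 2 and 3 and -0.34, -0.17 and -0.71 in JPHZW 1, 2 and 3.

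Of the remaining lower lists, PPAR signalling and targets had Pparg and Ppara (-1.86) foremost. In the PPAR list, none of the 23 tested members passed, with 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00960, and adjusted p = 0.348 with an estimated correlation). Camera gave an adjusted p of 0.152 without JPHZW 2. Goblet cell and mucus genes had Muc2 at -1.25. In the goblet cell list, none of the 20 tested members passed, with 2 lower adjusted over the list alone (camera adjusted p = 0.0359, and adjusted p = 0.490 with an estimated correlation). Camera gave an adjusted p of 0.0670 without UC model 1 and 0.190 without UC model 2. Under other settings the lower call ended for PPAR genes with FPKM of at least 5 (adjusted p = 0.110) and without control 1 and JPHZW 2 (0.133), for goblet cell genes with FPKM of at least 5 (0.0912) and after quantile normalization (0.446), and for the absorptive colonocyte list without UC model 3 and JPHZW 3 (0.370).

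Immune and stromal lists were higher in JPHZW libraries, mostly where single libraries stood out. B cell and germinal centre genes had a median of 3.76, with Blk at 3.82. In the B cell list, none of the 13 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.000167, and adjusted p = 0.730 with an estimated correlation). The list had an adjusted p of 0.0728 and a median of 0.98 without JPHZW 2, which held the highest score. MHC class II genes, with H2-Ob at 3.47, were higher. In the MHC class II list, none of the 10 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.00119, and adjusted p = 0.730 with an estimated correlation). Camera's adjusted p was 0.0910 without UC model 3 and 0.106 without JPHZW 2. Monocyte and macrophage genes were higher, with Ccr2 at 2.04 ± 0.42. In the monocyte and macrophage list, none of the 19 tested members passed, with 1 higher adjusted over the list alone (camera adjusted p = 0.000533, and adjusted p = 0.730 with an estimated correlation). The list had an adjusted p of 0.278 and a median of 0.12 without JPHZW 3. T and NK cell genes, with Icos at 2.28, were higher. In the T and NK cell list, none of the 13 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.730 with an estimated correlation). Its adjusted p was 0.374, 0.0970 and 0.106 without UC model 3, JPHZW 2 and JPHZW 3. Without UC model 2 the medians of the T and NK cell and MHC class II lists were 1.57 and 1.93. NF-kB pathway genes had a median of 0.24, with Nfkbiz at 0.91 and Nfkbie at 1.37. In the NF-kB list, none of the 23 tested members passed, with 2 higher adjusted over the list alone (camera adjusted p = 0.0198, and adjusted p = 0.730 with an estimated correlation). The adjusted p became 0.494 without UC model 2 and 0.207 without JPHZW 3. Immediate early and heat shock genes were higher, with Nr4a1 at 1.71 ± 0.36. In the immediate early list, none of the 15 tested members passed, with 1 higher adjusted over the list alone (camera adjusted p = 8.08e-05, and adjusted p = 0.348 with an estimated correlation).

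Among stromal lists, extracellular matrix and remodelling had Tgfb1 at 1.01. In the matrix list, none of the 24 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.00160, and adjusted p = 0.730 with an estimated correlation). Camera gave an adjusted p of 0.0855 without UC model 1 and 0.619 without JPHZW 3, the library with the highest score. The median of 0.91 was 0.01 without it and 2.19 without UC model 3. Fibroblast genes, with Mfap5 at 3.08, were higher. In the fibroblast list, none of the 13 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.00393, and adjusted p = 0.730 with an estimated correlation). Camera's adjusted p was 0.312 and the median 0.66 without JPHZW 3. Endothelial genes, with the lymphatic receptor Flt4 at 1.82, were higher. In the endothelial list, none of the 13 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.00566, and adjusted p = 0.730 with an estimated correlation). The list had an adjusted p of 0.0505 without UC model 2 and 0.315 without JPHZW 3. Smooth muscle genes, with Lmod1 at 1.03, were higher. In the smooth muscle list, none of the 13 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.0366, and adjusted p = 0.730 with an estimated correlation). Its adjusted p was 0.0932, 0.254, 0.275 and 0.315 without UC model 1, UC model 3, JPHZW 1 and JPHZW 3. Under other settings the higher call ended on the TPM scale for T and NK cell, endothelial, matrix, fibroblast and smooth muscle genes (adjusted p = 0.0845, 0.0948, 0.0958, 0.105 and 0.251), and without control 1 and JPHZW 2 for MHC class II (0.0572) and T and NK cell genes (0.0706). Without UC model 3 and JPHZW 3 it ended for T and NK cell, fibroblast and smooth muscle genes (0.855, 0.0906 and 0.803), and the limma, stricter filter, TMM-free and covariate settings ended it for smooth muscle, with adjusted p from 0.0563 to 0.112.

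Neutrophil and cytokine genes were not called but had positive medians, and no member of an uncalled list passed over all genes. Adjusted over the list alone, 1 regenerative gene was higher and 1 lower, and none passed in the other uncalled lists. With an estimated correlation the adjusted p of these lists lay between 0.730 and 0.951. Neutrophil genes had a median of 0.98 and an adjusted p of 0.0629, which was 0.0428, 0.0446, 2.06e-05, 0.0125 and 0.0242 without control 1, control 2, UC model 3, JPHZW 1 and JPHZW 2. The median was 2.70 without UC model 3 and -0.98 without JPHZW 3. Cytokine and chemokine genes had a median of 1.26 and an adjusted p of 0.0674, which was 0.00280, 0.00708 and 0.00146 without UC model 3, JPHZW 1 and JPHZW 2, and the median was 2.19 without UC model 3 and -0.78 without JPHZW 3. The interferon response list had a median of -0.34 and a mean of -0.29 where camera's direction was higher (adjusted p = 0.862), and its median was 0.96 without UC model 1 (adjusted p = 3.15e-06) and -0.79 without UC model 3 (adjusted p = 0.00366). Epithelial antimicrobial defence had an adjusted p of 0.205, and of 0.0324 and 0.0300 without UC model 2 and JPHZW 3. Mitochondrially encoded transcripts (0.0872) passed without UC model 3 (0.000791) or JPHZW 2 (0.0242). Proliferation (0.0674) passed without control 3, UC model 2, UC model 3 or JPHZW 2 (0.0353, 0.0363, 0.00190 and 0.00147). The enteric neuron list (0.0629) passed without control 2, UC model 3, JPHZW 1 or JPHZW 3 (0.0457, 0.0174, 0.0345 and 0.00276).

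The other lists that camera did not call between JPHZW and UC model libraries were regenerative epithelium (adjusted p = 0.264, and 0.0159 without UC model 3), distal position (0.264, and 0.0314 and 0.0406 without UC model 1 and JPHZW 3), adipocyte (0.292, and 0.0373 without UC model 3), stem cell and Wnt (0.678), unfolded protein response (0.753), inflammasome and pyroptosis (0.881), plasma cell (0.870), tuft cell (0.696), erythroid (0.312) and circadian clock (0.368). The mast cell and skeletal muscle lists, untested by camera, had medians of 0.89 and -0.23. Camera's direction differed in sign from the median, the mean or both for stem cell and Wnt (-0.17 and 0.00), inflammasome (-0.03 and 0.17) and plasma cell genes (-0.21 and 0.23). In all, camera called 19 of 36 lists, 10 higher and 9 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.190. Other settings also called lists not called here: neutrophil in 8 settings (adjusted p from 8.44e-07 to 0.0421), cytokine and chemokine in 5 (0.00164 to 0.0455), enteric neuron in 9 (0.000914 to 0.0400), proliferation in 5 (0.00120 to 0.0416), mitochondrially encoded in 3 (0.0192 to 0.0255) and adipocyte in 2 (0.0304 and 0.0494). Without UC model 3 and JPHZW 3 the antimicrobial and regenerative lists were called (2.96e-07 and 0.0188).

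The comparison of the JPHZW with control libraries shows where the treated colon still differed from the normal one. Inflammatory genes were among those that rose. S100a9 and Cxcr2, both of neutrophils, and the chemokine Cxcl2 had 0 counts in control libraries and were at least 1672-fold, 229-fold and 246-fold higher against the floor of 3 counts over the group. S100a8 had 2 control counts, a ratio of 2213 (612 to 18277), and haptoglobin Hp went from 0.131 ± 0.128 to 271 ± 412 CPM. These folds rested largely on JPHZW 3, without which S100a9, Cxcr2 and Cxcl2 were at least 272-fold, 73.1-fold and 75.8-fold higher, S100a8 had a ratio of 399 and Hp a log2 change of 7.91. None of the 5 passed then (adjusted p = 0.0908, 0.115, 0.114, 0.0756 and 0.112). Ang4 fell from 313 ± 130.4 to 2.17 ± 2.66 CPM (log2 -7.18 ± 1.26, adjusted p = 0.0187), and the metal transporter Slc30a10 (-6.24), Bex4 (-4.44 ± 0.50, adjusted p = 0.0136) and Ces1b (-4.36) fell too, with Klk1b4, of a kallikrein family with shared sequence, at a control to JPHZW ratio of 28.1 (7.40 to 239). The test called 2402 genes, 1460 higher and 942 lower, with 4790 at an unadjusted p under 0.05 and 3817 called by DESeq2. Il1b (log2 8.52 ± 1.73, adjusted p = 0.0239), Tnf (2.26, 0.0401) and Nfkb1 (0.44, 0.0460) rose, while Rela (0.45, 0.217), Nfkbia (0.59, 0.173) and Pparg (0.06, 0.871) did not pass, the last at -0.09 without control 2 and -0.08 without JPHZW 3. The calls of Nfkb1, Tnf and Il1b were lost in 16 of 28, 11 of 28 and 3 of 27 alternatives. With 1 library left out, Nfkb1 passed without UC model 3 alone (adjusted p = 0.0479), and Tnf without UC model 1, 2 and 3 alone (0.0426, 0.0409 and 0.0496). Il1b was at 6.31 without JPHZW 3 (adjusted p = 0.0468) and 9.30 without control 1 (0.0669), Ang4 at -8.95 without JPHZW 3 (0.0353), Hp at 11.82 without control 2 (0.0951), and Slc30a10 and Ces1b at -8.49 and -6.36 without JPHZW 2 (0.0130 and 0.0105). Without control 1, 2 and 3 the count was 443, 1176 and 0, and without JPHZW 1 and 3 it was 415 and 375, where edgeR's 0 without control 3 left 3613 genes at an unadjusted p under 0.05. Of the 13 named genes that passed, 3, 5 and 0 passed without control 1, 2 and 3, 9, 11 and 13 without UC model 1, 2 and 3, and 4, 11 and 4 without JPHZW 1, 2 and 3. The libraries of the groups did not overlap for 5552 genes, 41.0% where chance gives 10%.

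Immune gene lists were higher in JPHZW than in control libraries. For monocytes and macrophages 14 of 19 tested members rose, 5 did not pass, with 18 higher adjusted over the list alone, with Ccr2 (1.91 to 37.9 CPM), Lyz2 (31.4 to 412), C1qb and C1qa among them (camera adjusted p = 1.13e-16, and adjusted p = 0.423 with an estimated correlation). For neutrophils 8 of 11 tested members rose, 3 did not pass, with 10 higher adjusted over the list alone, including Csf3r (log2 7.75) and lactoferrin Ltf (4.43) (camera adjusted p = 3.47e-07, and adjusted p = 0.425 with an estimated correlation). Of cytokines and chemokines 12 of 15 tested members rose, 3 did not pass, with 15 higher adjusted over the list alone, with Ccl2 (6.58) and Cxcl9 (7.34) beside Il1b (camera adjusted p = 8.91e-08, and adjusted p = 0.425 with an estimated correlation). The median was 6.58, or 5.54 with members at 0 to 3 control counts at their bound or ratio. In the NF-kB pathway 9 of 23 tested members rose, 14 did not pass, with 10 higher adjusted over the list alone, including Nfkbie (2.44) and Vcam1 (3.45) (camera adjusted p = 2.49e-05, and adjusted p = 0.425 with an estimated correlation). For T and NK cells 8 of 13 tested members rose, 5 did not pass, with 10 higher adjusted over the list alone, with Ctla4 (5.04) and Gzmb (4.45) (camera adjusted p = 2.46e-07, and adjusted p = 0.425 with an estimated correlation). Of plasma cell genes 2 of 6 tested members rose, 4 did not pass, with 4 higher adjusted over the list alone, Prdm1 (2.84) and Jchain (2.41) (camera adjusted p = 0.00470, and adjusted p = 0.423 with an estimated correlation). MHC class II, with H2-DMb1 at 1.81, was higher though none of the 10 tested members passed and none passed adjusted over the list alone (camera adjusted p = 0.00525, and adjusted p = 0.559 with an estimated correlation), and had an adjusted p of 0.163 without JPHZW 2. Of B cell and germinal centre genes 1 of 13 tested members rose, 12 did not pass, with 1 higher adjusted over the list alone, the chemokine Cxcl13 (3.48) (camera adjusted p = 0.0236, and adjusted p = 0.693 with an estimated correlation). Without JPHZW 2 the median was -0.51 (adjusted p = 0.625), and without control 2 and control 3 the adjusted p was 0.117 and 0.0637. Other medians moved by over 1.5 times. Without JPHZW 3 those of the neutrophil and cytokine lists were 6.35 and 4.16, and without control 2 they were 10.15, with Il1r2 left at 0 control counts, and 7.38. Without JPHZW 2 those of the plasma cell and MHC class II lists were 1.43 and 1.21. Without control 1 those of the B cell, MHC class II, T and NK cell and plasma cell lists were 4.97, 3.45, 3.62 and 2.98.

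Stromal and regenerative genes were higher too. Among extracellular matrix and remodelling genes 16 of 24 tested members rose, 8 did not pass, with 24 higher adjusted over the list alone, with Tgfb1 (2.09), Col6a3 (3.46) and Col1a2 (108 to 2396 CPM) (camera adjusted p = 4.95e-11, and adjusted p = 0.425 with an estimated correlation). Of endothelial genes 7 of 13 tested members rose, 6 did not pass, with 12 higher adjusted over the list alone, with Esam (1.66) and Cdh5 (2.69) (camera adjusted p = 2.77e-06, and adjusted p = 0.425 with an estimated correlation). Of fibroblast genes 5 of 13 tested members rose, 8 did not pass, with 11 higher adjusted over the list alone, with Thy1 (2.93) and Pdpn (3.14) (camera adjusted p = 1.66e-05, and adjusted p = 0.425 with an estimated correlation). Of smooth muscle genes 2 of 13 tested members rose, 11 did not pass, and none passed adjusted over the list alone, Kcnmb1 (1.72) and Myocd (2.35) (camera adjusted p = 0.000686, and adjusted p = 0.551 with an estimated correlation). Of enteric neuron, glia and interstitial cell of Cajal genes 5 of 15 tested members rose, 10 did not pass, with 10 higher adjusted over the list alone, with Nos1 (2.39) and Ret (1.56) (camera adjusted p = 0.000486, and adjusted p = 0.485 with an estimated correlation). For the regenerative epithelium 3 of 13 tested members rose, 10 did not pass, with 4 higher adjusted over the list alone: Ccn1 (2.52 ± 0.32), Plaur (3.42) and Ereg (5.82) (camera adjusted p = 0.00507, and adjusted p = 0.425 with an estimated correlation). Epithelial antimicrobial defence was higher with Slpi (6.78), Nos2 (5.04) and Duox2 (0.99) up and Ang4 down. In the antimicrobial list, 4 of 16 tested members rose and 2 fell, 10 did not pass, with 10 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0389, and adjusted p = 0.425 with an estimated correlation). Its adjusted p was 0.0747, 0.0843, 0.0668 and 0.0653 without control 1, control 2, UC model 3 and JPHZW 2. JPHZW 3 held the highest neutrophil, fibroblast and matrix scores of the 9 libraries, and without it the matrix and fibroblast medians were 2.70 and 2.24. Without control 2 the medians of the matrix, fibroblast, endothelial and smooth muscle lists were 4.92, 4.02, 2.44 and 2.21.

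Energy metabolism and epithelial transport genes were lower in JPHZW than in control libraries. Of fatty acid oxidation and ketogenesis genes 13 of 18 tested members fell, 5 did not pass, with 14 lower adjusted over the list alone, with Acads (-1.05) and Acat1 (-0.79) (camera adjusted p = 6.84e-08, and adjusted p = 0.423 with an estimated correlation). Among nuclear oxidative phosphorylation genes 14 of 23 tested members fell, 9 did not pass, with 22 lower adjusted over the list alone, with Cox5b (-0.75 ± 0.11) and Cox5a (-0.61) (camera adjusted p = 8.91e-08, and adjusted p = 0.425 with an estimated correlation). Of mitochondrially encoded transcripts 1 of 13 tested members fell, 12 did not pass, and none passed adjusted over the list alone, mt-Co2 (-0.82) being the 1 (camera adjusted p = 0.000812, and adjusted p = 0.538 with an estimated correlation). For xenobiotic metabolism 8 of 25 tested members fell, 17 did not pass, with 10 lower adjusted over the list alone, with Sult1a1 (-2.42 ± 0.25) and Maob (-1.53) (camera adjusted p = 2.46e-07, and adjusted p = 0.423 with an estimated correlation). Of stem cell and Wnt genes 1 of 14 tested members rose and 6 fell, 7 did not pass, with 1 higher and 7 lower adjusted over the list alone: Rnf43 (-0.99), Ascl2 (-2.39) and Cdca7 (-0.93) fell and Nkd1 (1.82) rose (camera adjusted p = 0.00489, and adjusted p = 0.425 with an estimated correlation). Of junction genes 2 of 18 tested members fell, 16 did not pass, with 2 lower adjusted over the list alone, Cgn (-0.59) and Marveld2 (-0.73) (camera adjusted p = 0.00303, and adjusted p = 0.458 with an estimated correlation). Of absorptive colonocyte and ion transport genes 1 of 23 tested members rose and 5 fell, 17 did not pass, with 1 higher and 7 lower adjusted over the list alone, with Car2 (1348 to 432 CPM), Slc20a1, the chloride channel Cftr (-1.22) and Slc16a1 down (camera adjusted p = 0.00555, and adjusted p = 0.538 with an estimated correlation). The adjusted p was 0.0788 without control 1. The genes shared by all epithelial cells stood at 0.30, 0.13 and 0.30 in control 1, 2 and 3, above the -0.34, -0.17 and -0.71 in JPHZW 1, 2 and 3.

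Single genes also changed in lists that camera did not call. Scd1 (2.32), Cd36 (1.74) and Lpl (2.72) rose and Ppard (-0.90) fell in PPAR signalling and targets, where 16 of 23 members did not pass, and 5 higher and 2 lower passed adjusted over the list alone (camera adjusted p = 0.951, and adjusted p = 0.990 with an estimated correlation). Muc2 (1.33) rose and Klk1 (-1.44) and Clca1 (-2.26) fell in the goblet cell and mucus list, where 17 of 20 members did not pass, and 1 higher and 2 lower passed adjusted over the list alone (camera adjusted p = 0.951, and adjusted p = 0.990 with an estimated correlation). Gpx3 (3.15), Hmox1 (3.16) and Sod3 (3.11) rose and Sod1 (-0.68) fell among oxidative stress and Nrf2 genes, where 13 of 17 members did not pass, and 3 higher and 1 lower passed adjusted over the list alone (camera adjusted p = 0.951, and adjusted p = 0.990 with an estimated correlation). Mefv (4.29) rose and Pycard (-0.92) and Gsdmc2 (-3.58) fell in the inflammasome list, where 8 of 12 members did not pass, and 2 higher and 2 lower passed adjusted over the list alone (camera adjusted p = 0.580, and adjusted p = 0.781 with an estimated correlation). Gbp2, Iigp1 and Gbp4 (2.92, 3.98 and 2.21) rose in the interferon response, where 20 of 23 members did not pass, and 3 higher passed adjusted over the list alone (camera adjusted p = 0.0866, and adjusted p = 0.836 with an estimated correlation). The interferon list passed without control 3, UC model 1 or UC model 3 (0.0164, 0.0197 and 0.0229). Nr4a1 (2.77), Dusp1 (1.95) and Ier3 (2.16) rose among immediate early and heat shock genes, where 12 of 15 members did not pass, and 3 higher passed adjusted over the list alone (camera adjusted p = 0.0657, and adjusted p = 0.559 with an estimated correlation). The immediate early list passed without control 1, control 3, UC model 3, JPHZW 1 or JPHZW 3 (0.0344, 0.0111, 0.0282, 0.0486 and 0.0361). Nr1d2 (1.17) and Tef (1.37) rose and Arntl (-1.24) and Npas2 (-1.48) fell in the circadian clock list, where 8 of 13 members did not pass, and 2 higher and 3 lower passed adjusted over the list alone (camera adjusted p = 0.911, and adjusted p = 0.990 with an estimated correlation). Asns (0.93) and Atf6 (0.68) rose in the unfolded protein response, where 14 of 16 members did not pass, and none passed adjusted over the list alone (camera adjusted p = 0.208, and adjusted p = 0.707 with an estimated correlation). Fabp4 (1.77) rose and Acvr1c (-1.24) fell in the adipocyte list, where 8 of 10 members did not pass, and 1 higher and 1 lower passed adjusted over the list alone (camera adjusted p = 0.0876, and adjusted p = 0.559 with an estimated correlation). The adipocyte list passed without control 3 (0.0114) or JPHZW 2 (0.0450). Over all genes no member passed for proliferation (0.676), enteroendocrine (0.951), tuft (0.951), erythroid (0.949) and distal position genes (0.985), values that are camera's adjusted p, nor for mast cell and skeletal muscle genes, with medians of 2.49 and -0.19. Adjusted over the list alone, 2 mast cell genes were higher and none passed in the other lists, whose adjusted p with an estimated correlation lay between 0.990 and 0.992. Camera's direction differed in sign from the median, the mean or both for PPAR (-0.12 and 0.49), goblet (0.18 and 0.20), Nrf2 (-0.13 and 0.47), inflammasome (-0.34 and 0.33), enteroendocrine (-0.07 and 0.45) and distal position genes (-0.11 and -0.06). Camera called 22 of 36 lists, 15 higher and 7 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.423. Under other settings the call ended on the TPM scale for B cell, MHC class II, regenerative and antimicrobial genes (adjusted p = 0.144, 0.0528, 0.0670 and 0.577), after quantile normalization for absorptive colonocyte, mitochondrially encoded and junction genes (0.190, 0.538 and 0.0990), and with FPKM of at least 5 for enteric neuron and antimicrobial genes (0.0689 and 0.0697). Without control 1 and JPHZW 2 it ended for absorptive colonocyte and antimicrobial genes (0.0898 and 0.0905), and for the antimicrobial list also with limma on log2(FPKM + 1), with pseudocounts of 0.1 and 0.01 and without TMM (0.206, 0.0941, 0.0665 and 0.0576). Other settings also called lists not called here: immediate early in 6 settings (adjusted p from 0.00348 to 0.0388), the interferon response in 4 (0.00563 to 0.0436), adipocyte in 4 (0.0125 to 0.0467), the unfolded protein response after quantile normalization (0.00391) and proliferation without control 1 and JPHZW 2 (0.0453).

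The design text also asks whether JPHZW acts on the genes changed in the model. Of the 770 genes called in the UC model, 71.0% had a JPHZW against UC model change of the opposite sign, 68.4% of the 443 that rose and 74.6% of the 327 that fell. Nupr1, Pparg, Muc2, Car1 and Plet1 were among those with the opposite sign, with log2 changes of -1.77, -1.29, -1.25, -4.24 and -1.25, of which Nupr1 passed. Genes that rose in the model had a median change of 2.24 there and of -0.34 from the UC model to JPHZW, leaving 1.66 against control. Those that fell had medians of -0.96, 0.20 and -0.81. Both comparisons use the UC model libraries, so opposite signs arise with no treatment effect. In 40 simulated draws where JPHZW equalled the UC model, the share was 63.6% on average and 61.0% to 65.4% in range. Those draws called 2176 to 2357 genes in the UC model where 770 were observed, so their share covers more genes than the observed one, and with no effect at all it was 100% of a mean of 0.0750 calls. Across genes, which are not independent replicates, the covariance of the 2 sets of changes was -0.108, against -0.103 simulated with no effect, a difference of -0.00491. The draws with JPHZW equal to the UC model gave -0.125 to -0.0776, and a correlation of -0.223 to -0.145 where -0.148 was observed, so on these measures the data showed no excess of opposite changes. Leaving out JPHZW 2 gave a share of 49.0% and leaving out control 3 gave 100% of 16 genes.

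Of the 770 genes called in the UC model, 517 were called in the same direction in JPHZW against control. Of those that rose in the UC model, 295 also rose in JPHZW libraries, where 47.8 would be shared by independent lists, and of those that fell 222 also fell, where 22.8 would be. Draws with JPHZW equal to the UC model shared 1589 to 1735, with 2176 to 2357 genes called in the UC model. The covariance of the fold changes was 1.10, against 0.103 simulated with no effect, a difference of 0.997, and 1.38 simulated with JPHZW equal to the UC model. The correlation was 0.838, against 0.930 in the latter. The 3 control libraries could not be split with at least 2 in each part, and part of the excess can come from sharing them.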

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

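Limma on log2(FPKM + 1) was the fit fixed before the data were examined, and became an alternative once the files proved to hold counts. Alternatives chosen after seeing the data were DESeq2, library totals without TMM, the distal position score as a covariate, and leaving out UC model 3 with JPHZW 3 or control 1 with JPHZW 2. Il6 was under the filter and had no value. Each other named gene had one in 26 to 28 of the 28 alternatives, and those that passed kept their sign in all of these: 17 in the UC model against control, 2 in JPHZW against the UC model and 13 in JPHZW against control. DESeq2 called 15, 2 and 9 of them. Where a value below differs from the reported one, the cause was not tested, except that omissions and stricter filters use fewer libraries or genes.

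Genes called in the UC model against control (770) were 171 with the replicate block, 1168 with only the 2 groups compared, 1643 with library weights, 2307 at an adjusted p under 0.10, 2679 by DESeq2, 191 with the distal position covariate, 16 without control 1 and JPHZW 2, and 16 to 1366 with 1 library left out. Genes called in JPHZW against the UC model (3) were 6 with a pseudocount of 0.1, 13 with no filter, 7 with FPKM of at least 5, 5 on the TPM scale, 10 after quantile normalization, 1876 with library weights, 48 at an adjusted p under 0.10, 572 by DESeq2, 1 with the covariate, 18 without UC model 3 and JPHZW 3, and 0 to 17 with 1 library left out. They were 0 by edgeR with median-of-ratios factors, with the replicate block, with only the 2 groups and without control 1 and JPHZW 2, where 1884, 1582, 1537 and 2120 genes had an unadjusted p under 0.05. Genes called in JPHZW against control (2402) were 1461 with FPKM of at least 5, 447 with the replicate block, 1291 with only the 2 groups, 6512 with library weights, 1549 with at least a 2-fold change, 3972 at an adjusted p under 0.10, 3817 by DESeq2, 621 without UC model 3 and JPHZW 3, and 0 to 3308 with 1 library left out. The library weights gave JPHZW 1 a weight of 18.0 against 0.324 to 1.30 for the others, and their estimate stopped before its convergence tolerance. In the replicate block the libraries with the same number had r from -0.52 to 0.32 between groups. All 6 such pairs with control were negative, while the 3 of the UC model with JPHZW were positive (0.12, 0.10 and 0.32, others -0.42 to 0.35), so whether the numbers pair the mice in that comparison stayed open.

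The share of UC model calls moving back under JPHZW (71.0%) was 76.5% with limma on log2(FPKM + 1), 67.2% with a pseudocount of 0.01, 66.8% with no filter, 74.7% after quantile normalization, 80.1% with the replicate block, 76.0% without a trend, 65.3% with library weights, 59.0% by DESeq2, 84.3% with the covariate, 78.7% without UC model 3 and JPHZW 3, and 93.8% without control 1 and JPHZW 2. With UC model 1, 2 or 3 held out of the calls it was 61.4%, 59.7% and 84.2%, and with 1 library left out 49.0% to 100%.

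Gene lists called by camera numbered 15 to 18, 15 to 24 and 20 to 24 with 1 library left out of the UC model against control, JPHZW against the UC model and JPHZW against control, and 0, 0 and 0 of limma's camera tests passed with an estimated correlation, against 17, 19 and 22 with the preset one. The interferon response list in JPHZW against the UC model, which was not called, was lower without UC model 3 and JPHZW 3 (median -0.75, adjusted p = 0.00195) and without UC model 3 (-0.79, 0.00366), and higher without UC model 1 (0.96, 3.15e-06). A further 33 values of 6 gene results and 154 values of 35 list results changed sign while past the threshold in neither setting. The genes were Nfkbia, Tnf, Nfkb1, Rela and Il1b in JPHZW against the UC model and Pparg in JPHZW against control. Among values of named genes, 149, 26 and 90 lost and 12, 33 and 3 gained a call in the 3 comparisons, and among list values 40, 61 and 46 lost and 22, 59 and 26 gained one.

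The scaling shifts all genes together. On the TPM scale the median change of all genes tested was 0.126 in JPHZW against the UC model and 0.168 in JPHZW against control, and after quantile normalization -0.127 in JPHZW against control, where the reported fit had 0.0161 and -0.0422. The share of higher calls in the UC model and in JPHZW against control was 57.5% and 60.8%, 67.7% and 83.4% on the TPM scale, and 40.3% and 39.6% after quantile normalization. With 3 libraries a group the simulated 2-fold changes were mostly missed, so changes of this size could not be excluded for genes that did not pass.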

Other observations

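All tests in this part were chosen after the result was seen. The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. In the UC model against control the real split called 770 genes and the highest of the others 0, in JPHZW against the UC model 3 and 2, and in JPHZW against control 2402 and 0. In each comparison only the real split gave as many by edgeR. DESeq2 was not run on splits. Real splits left 4001, 1876 and 4790 genes at an unadjusted p under 0.05, and others up to 859, 1988 (above the real one) and 1856.

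Of 13 homeobox genes of paralogue groups 4 to 9, a grouping made after the values were seen and not tested as a group, 9 were higher in the UC model (5 passed) and 4 lower (none passed), with a median log2 of 1.68, while Hoxb13 was low in 3 of 3 UC model libraries. Pieces taken farther from the anus in the UC model mice may account for the rise and the low Hoxb13. Across 23 Hox genes, which are not independent, paralogue group and fold change had a Spearman rho of -0.51 (permutation p = 0.0134). That met the rule first written but not a later condition, since genes following the distal score within groups were as low in 24 of 100 permutations (r = -0.49). The distal position list's median of -1.36 was 1.45 without control 2, so that list cannot decide it. Loss of epithelium stays open: 1.95 (SD of members 1.23), the highest median of 4 gut wall cell lists, exceeded the 13 genes' 1.68. The 5 genes that passed (3.01 to 6.55) were picked by their rise and cannot decide this. A change of Hox expression in colitis itself cannot be told apart from a difference in position. The same 13 genes had a median of 1.01 in JPHZW against control, where the mice also had colitis, and of -1.34 in JPHZW against the UC model.

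Genes changed in the UC model moving back in JPHZW libraries may come from noise of the UC model libraries: the share of 71.0% lay above the 65.4% that simulations without a treatment effect reached, but these called 2176 to 2357 genes against 770, and the covariance of -0.108 lay within their -0.125 to -0.0776. With the UC model library that sets the direction held out of the calls, the lowest share was 59.7%. A difference in colon position between the groups could contribute, but with the distal score as a covariate the share of UC model calls moving back under JPHZW was 64.3% for the same genes and 84.3% for those called under it, values on opposite sides of 71.0%. The JPHZW treatment stays open: the share was 71.4%, 85.7% and 47.0% in JPHZW 1, 2 and 3. The 3 explanations cannot be told apart with 3 libraries a group.

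For the loss of epithelium, earlier tests were the pan-epithelial median of -0.16 over 15 genes (range -0.68 to 1.14), then Hoxb13 against its error. The noise test was first the simulated share and the position test the Hox rho in JPHZW against the UC model, 0.59 (permutation p = 0.00314), before the tests above replaced them, and the test of the treatment was added last.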
